A study of Drosophila melanogaster with 4 samples.

How the data were processed

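Chromatin immunoprecipitation followed by sequencing was performed on Drosophila melanogaster embryos, with 2 libraries of TBP-bound DNA and 2 libraries of input DNA, numbered 1 and 2 in each group by their titles. Per the labels, embryos were staged 0 to 8 h and carried a GFP-tagged extradenticle transgene. The extraction text attached to the same samples describes an 8 to 16 h collection from a different strain, with cross-linking in 1.8% formaldehyde for 15 min. The stage and strain fields were followed here, and which of them applies to the cross-linking conditions is not known. The labels do not say whether replicates came from separate collections, and the sex of the embryos is given as unknown.

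One processed file was analysed, a list of peaks in GFF version 3 for the whole series. Per the file headers, positions are on FlyBase release 5, and the source field of each line names MACS, a peak caller that compares immunoprecipitated with control reads. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5, without versions for BWA and MACS2 and without saying what each was used for. The threshold, the treatment of duplicate and multiply mapped reads, and whether replicates were pooled before calling are not given in the sources used here. Each deposited peak has a start, an end and a score. The score was deposited by the authors without a scale, so whether it is a p-value, a q-value or another measure is unknown. It was used only to rank and describe peaks within this list. Lists of this kind depend on those settings. The narrowest peak was 201 bp (71 peaks), the smallest gap between peaks was 50 bp, no peaks overlapped and the lowest score was 6; whether the calling set these limits is not known. Low scores came in repeated values, with 602 distinct values among 2711 peaks scoring below 20. Depth per sample is unknown, so no counting interval or detection limit per peak could be given. With 1 list and no values per replicate, no spread between replicates could be measured.

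The gene table supplied for this work belongs to release 6 of the genome, whereas the peaks are on release 5. Coordinates were not converted between releases and no release 5 sequence was used. The planned tests of peaks at transcription start sites, of gene features, of head-to-head promoters, of core promoter motifs and of 25 gene lists were therefore not run. The gene table was used only for gene names and neighbours.

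Before the data were examined, the groups, the tests of peak density by arm and of peak spacing, their main alternatives and the rule for named items were fixed. With no annotation of the same build, that rule named the 10 highest-scoring and the 10 widest peaks by coordinates. Arm lengths were to come from the file header or a matching reference. Neither gave them, so the span from the first to the last peak of each arm was used. Density on each of the 6 arms was compared with the other arms by an exact two-sided binomial test with exact 95% intervals and Benjamini-Hochberg adjustment over 6 arms. Because peaks cluster, 100 kb and 500 kb windows were also permuted (100000 resamples, difference of means). Spacing was compared with 1000 random placements of the same peaks within their arms, keeping the first and last positions and the minimum gap. Pairs of peaks by distance used 100 such placements. Medians were compared by permutation (20000 resamples), with intervals from order statistics. The 90th percentiles were compared by permutation (10000 resamples), with intervals from 2000 bootstrap draws. Runs of wide peaks were peaks of at least 3000 bp with starts at most 15000 bp apart. The exact test is over-precise where peaks cluster, as tests on simulated data showed. The window permutations, score comparisons by arm, pair distances, dense windows, wide-peak runs and the comparison of Uextra with the arms were added after the data had been seen.

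The tests were checked on simulated lists of 7303 peaks on the real arm spans. With X density set to 0.8 times that of the other arms, the binomial test called X in 100% of 200 sets at a mean estimated fold of 0.80. With independent peaks and no difference it called X in 0.5% of sets. When the real 100 kb window counts were dealt at random over all arms, the binomial test called X in 19.5% of sets by adjusted p. The window permutation called X in 3.5% by unadjusted p. That rate is no check of the permutation, which deals windows in the same way. Such deals also remove any clustering beyond 100 kb. For the 1349 peaks of 2L, random placement set against other random placements gave a mean gap ratio of 1.01, as its construction requires. All of 20 clustered sets (100%) had a median gap below every random one. Each of their gaps had been, at random, either strongly shortened or lengthened, so only strong clustering was checked. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.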

Results

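TATA-binding protein (TBP) is the DNA-binding core of the general transcription factor TFIID. It was mapped by chromatin immunoprecipitation and sequencing in Drosophila melanogaster embryos labelled as 0 to 8 h. The question the series addresses is where TBP sits on the embryonic genome. By the labels, the embryos came from a strain with a GFP-tagged genomic copy of extradenticle, a homeodomain gene. The extraction text instead describes an 8 to 16 h collection from a different strain, and this conflict is unresolved. The antiserum was a rabbit polyclonal raised against TBP itself. The series holds 4 libraries, 2 from immunoprecipitated chromatin and 2 from input DNA. A single list of peaks was analysed for all of them, so read depths are unknown and no peak value has a replicate error. All p-values below describe the arrangement of peaks within this one list, because neither peaks nor genome windows are biological replicates. Positions are those of FlyBase release 5, and no peak was assigned to a gene.

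TBP peaks lay on all 6 chromosome arms considered. The list held 7769 peaks on 13 sequences, and 94.0% of them (7303) lay on 2L, 2R, 3L, 3R, 4 and X. Together the arm peaks covered 7.01 Mb, or 5.84% of the 120.1 Mb between the first and last peak of each arm. Median width over the whole list was 720 bp, and the middle 50% of peaks measured 397 to 1233 bp. On the arms 2480 peaks were narrower than 500 bp. The 8.85% that reached 2000 bp held 26.1% of the covered sequence. The deposited score, whose scale is not given in the sources used here, ranged from 6 to 400.63 with a median of 29.65. Wider peaks had higher scores on the arms (Spearman's rho = 0.835 and Pearson's r = 0.825 of the log values, across 7303 peaks, which are not independent replicates).

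The strongest TBP peak lay on 3L at 747913 to 750579, with a score of 400.63 and a width of 2667 bp. Ranks 2 to 4 were also on chromosome arms. These were the 2L peak at 7540454 to 7545308 (score 310.61), the 3R peak at 3298412 to 3301133 (308.07) and the 2L peak at 5236137 to 5238378 (304.51). The sixth and seventh ranks fell at 3L 22400193 to 22401696 (296.55) and at 2L 2749202 to 2756045 (290.39). The other 4 of the 10 highest scores belonged to Uextra, a collection of sequence not placed on any chromosome. They lay at 15561355 to 15562200, 12994321 to 12995161, 18979554 to 18980346 and 19186553 to 19187400, with scores of 297.43, 282.48, 278.68 and 277.91. All 4 were between 793 and 848 bp wide, whereas the 6 arm peaks in this group were between 1504 and 6844 bp wide.

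The widest TBP peaks were on chromosomes 2 and 3. The widest peak, on 2L at 8210281 to 8218092, spanned 7812 bp and scored 80.23. Next came the 2L peaks at 5976877 to 5983758 (6882 bp, score 117.27), 2749202 to 2756045 (6844 bp, 290.39) and 5225135 to 5231745 (6611 bp, 91.62). On 3L the widest were at 18983506 to 18990012 (6507 bp, 167.46) and 14747980 to 14754050 (6071 bp, 137.79). Arm 3R held the peaks at 2914475 to 2920667 (6193 bp, 66.67), 4875440 to 4881594 (6155 bp, 110.01) and 25682545 to 25688494 (5950 bp, 123.99). Arm 2R contributed its peak at 9472688 to 9479170 (6483 bp, score 249.21). Only the 2L peak at 2749202 was among both the 10 strongest and the 10 widest.

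**Figure D1:**
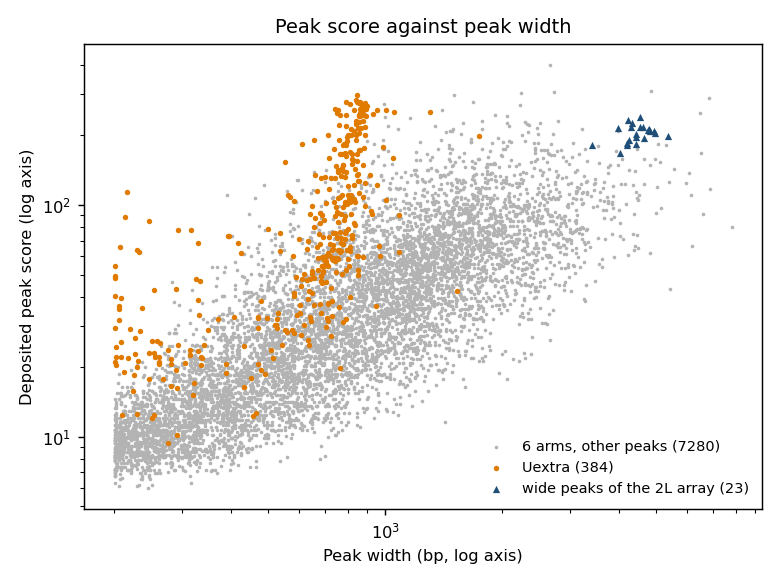
Deposited peak score (log axis) against peak width in bp (log axis) for every peak on the 6 arms, with Uextra peaks in orange and the wide peaks of the 2L array as blue triangles. Score rose with width on the arms (Spearman's rho = 0.835) and on Uextra (0.756), where 48.7% of peaks were from 700 to under 900 bp wide.

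The arms differed in how densely TBP peaks lay along them. Arm 2R was the densest of the long arms, with 69.8 peaks per Mb, 1.18 times the density of the other arms pooled (95% exact interval 1.12 to 1.25). The X chromosome, present once in males and in 2 copies in females, had the lowest density, at 52.7 peaks per Mb. That was 0.84 times the density of the other arms (0.79 to 0.89). The small chromosome 4, much of which is heterochromatic, carried 108 peaks at 83.9 per Mb (1.38 times the other arms, 1.13 to 1.67). Arms 2L, 3L and 3R had 0.96, 0.96 and 1.05 times the density of their other arms, which did not pass the exact test (adjusted p = 0.17, 0.17 and 0.15). In exact two-sided binomial tests with Benjamini-Hochberg adjustment over 6 arms, the adjusted p was 7.1e-08 for 2R, 7.4e-08 for X and 0.0028 for chromosome 4.

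That test treats each peak as independent, which clustered peaks are not. A permutation of 100 kb windows gave adjusted p-values of 0.017 for 2R, 0.017 for X and 0.18 for chromosome 4, and with 500 kb windows these were 0.07, 0.07 and 0.24. By the exact test the chromosome 4 difference also missed the threshold when peaks within 1 kb were merged (fold 1.18, adjusted p = 0.21). The same held among arm peaks above their own median score (exact test, fold 1.07, adjusted p = 0.63).

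**Figure D2:**
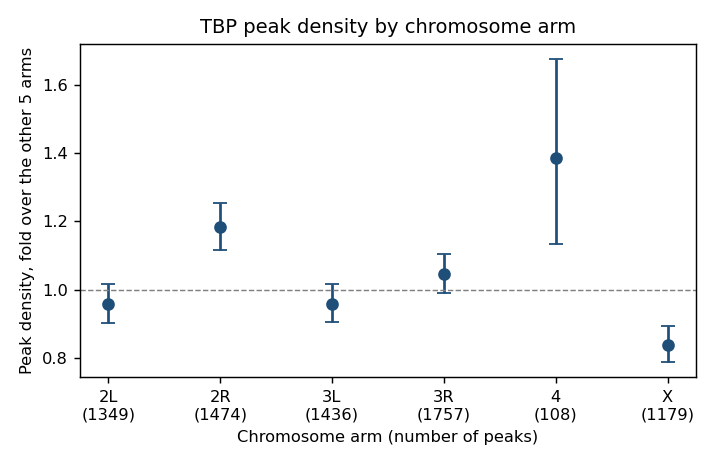
Peak density of each arm as a fold over the other 5 arms pooled; points are folds and bars are 95% exact binomial intervals, with the number of peaks under each arm. The X chromosome lies below 1 at 0.84 and 2R above it at 1.18, while the wide interval of chromosome 4 reflects its 108 peaks.

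Strong TBP peaks had lower scores on X than on the other arms. At the 90th percentile the score was 73.2 on X and 91.6 on the other arms, a ratio of 0.80 (95% bootstrap interval 0.75 to 0.85). The ratio was 1.00 at the 25th percentile, 0.93 at the median and 0.75 at the 99th percentile. Chromosome 4 had the lowest 90th percentile, 61.3 against 89.2 elsewhere (ratio 0.69, 0.59 to 0.81), and 3R a higher one, 94.7 against 86.2 (ratio 1.10, 1.03 to 1.17). Permutation tests of peaks gave adjusted p-values of 0.0006 for X, 0.015 for chromosome 4 and 0.015 for 3R. Those for 2L, 2R and 3L were 0.14, 0.28 and 0.34. In permutation tests of medians, X (26.83 against 28.83 elsewhere) and chromosome 4 (22.25 against 28.79) both missed the threshold (adjusted p = 0.21 for each). The median of 3R passed it (30.89 against 28.02, permutation test, adjusted p = 0.028). The 90th percentile was chosen as the measure after 7 percentiles of the scores had been seen. These tests permute single peaks and take no account of their clustering.

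TBP peaks lay in clusters. Neighbouring peaks on the arms were separated by a median gap of 4584 bp, against 10690 bp when the same peaks were placed at random within their arms (ratio 0.43). The medians of 1000 random placements ran from 10229 to 11067 bp (two-sided permutation p = 0.002, the smallest that these placements can give). Gaps shorter than 1 kb made up 25.1% of all gaps and 6.02% of random ones. Merging peaks within 1 kb left 5468 regions, with a median gap 0.56 times the random one. Pairs of peak centres 5 to 10 kb apart occurred 1.75 times as often as in random placements. At 20 to 50 kb the ratio was 1.32, and at 100 to 200 kb it was 1.05. It stayed above 1 at the largest distances, at 1.025 for 500 to 1000 kb (range over placements 1.017 to 1.033).

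**Figure D3:**
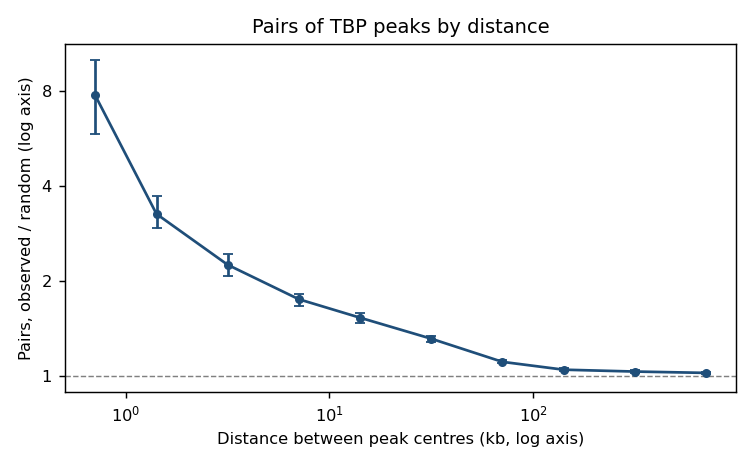
Number of pairs of peak centres at each distance (kb, log axis) divided by the number in random placements (log axis); points use the mean of 100 placements and bars the range over them. The ratio falls from 7.76 at 0.5 to 1 kb to 1.05 at 100 to 200 kb, and is 1.025 at 500 to 1000 kb.

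The 4 densest windows of TBP peaks lay on 3R, 2R and 3L. The window 3R 17400128 to 17500127 held 27 peaks, and 3R 21800128 to 21900127 held 26 with a median width of 1612 bp. Windows at 2R 9418279 to 9518278 and 3L 623816 to 723815 held 25 each. Over 1198 windows of 100 kb the mean was 6.08 ± 4.78 peaks (SD over windows). In 1000 random placements no window held more than 20 peaks. At the other extreme, 126 windows held no peak. The longest stretch without one was X 21942797 to 22409473, at 467 kb, followed by 366 kb at 3R 23784540 to 24150524 and 358 kb at 2L 16902286 to 17260405. These windows and gaps were ranked after the positions had been seen.

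**Figure D4:**
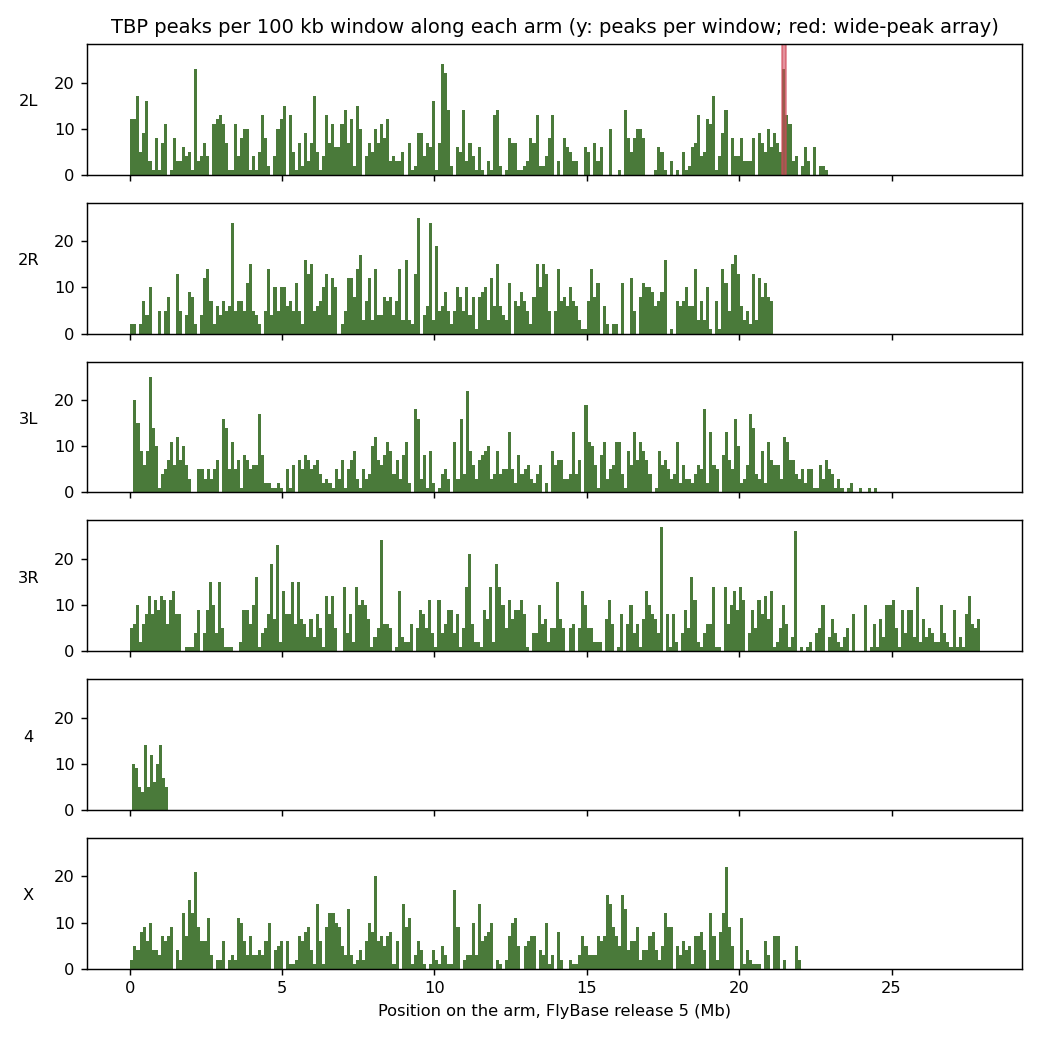
Peaks per 100 kb window (y axis, number of peaks) along the 6 arms (x axis, release 5 position in Mb), with the wide-peak array on 2L in red. Counts reach 27 on 3R, and peaks thin out towards the right-hand ends of 2L, 3L and X.

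An array of wide TBP peaks lay on 2L. Between 21416427 and 21539505, 23 peaks of at least 3000 bp followed each other at a median step of 5044 bp from start to start. Of the 22 steps, 21 averaged 5050 ± 201 bp (SD over steps), and the remaining one was 13632 bp. Peaks covered 85.5% of these 123 kb. The 23 peaks had a median width of 4422 bp and scores of 167.51 to 238.1, with a median of 207.85. The other 156 arm peaks of at least 3000 bp had a median score of 102.27. The array was singled out after the positions had been seen. Outside this region no run of such peaks with steps of at most 15 kb was longer than 2.

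**Figure D5:**
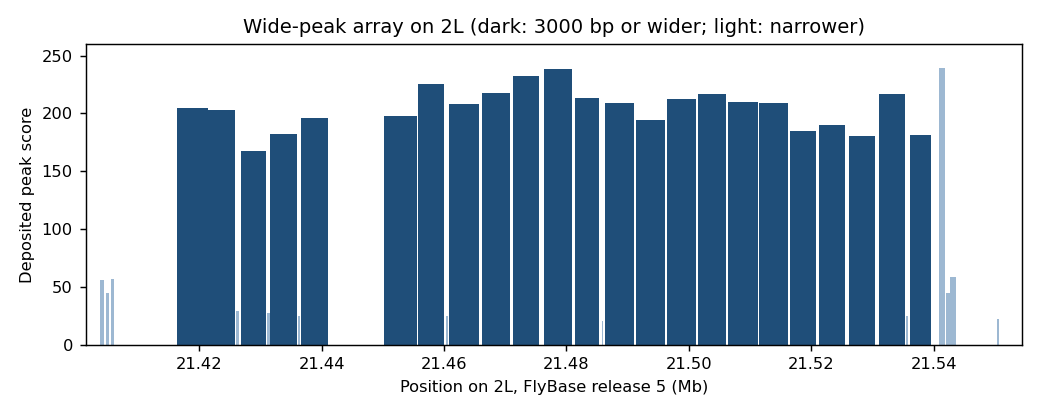
Peaks of the 2L array; each bar spans a peak on the x axis (release 5 position in Mb) and its height is the deposited score, with peaks of at least 3000 bp in dark blue. The 23 dark bars repeat every 5044 bp (median) at scores between 167.51 and 238.1, with 1 longer step of 13632 bp.

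Outside the arms, TBP peaks in the unplaced Uextra sequence scored higher than those on the arms. The 5 heterochromatic sequences held 56 peaks with a median score of 19.91 (95% interval of the median 18.36 to 24.12), against 28.43 (27.62 to 29.24) on the arms. The unplaced collection U held 26 peaks with a median score of 16.70. Uextra held 384 peaks, 4.94% of the list, with a median score of 64.24 (59.75 to 72.05), 2.26 times that of the arms. Among peaks above the median score the ratio was 1.44. A permutation test of the difference in medians gave p = 5e-05, the smallest that 20000 resamples can give. It treats single peaks as independent, which is not known to hold for the Uextra peaks. Median widths were 713.5 bp on Uextra and 725 bp on the arms (permutation p = 0.77). Of the 100 highest scores in the list, 46 were on Uextra and 54 on the arms.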

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

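All tests in this part were chosen, or their bounds were changed, after the results had been seen.

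Sequences outside the arm comparison with more than 3 listed peaks, the limit that a count of 0 allows, are given here as counts only, since passing that limit says nothing more about them. Uextra held 384, U held 26, and the heterochromatic sequences 3LHet, 2RHet, 3RHet, 2LHet and XHet held 21, 15, 9, 6 and 5.

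The Uextra peaks were narrower than arm peaks of similar score, although their width rose with score too (Spearman's rho = 0.756). The width of each Uextra peak was divided by that of the 50 arm peaks nearest in score. The median of these ratios was 0.467 (95% bootstrap interval 0.44 to 0.49). Stronger sites of the same shape as those on the arms would not give narrower peaks if the peaks were whole. They stay open, because scaffold ends, weighed below, could cut such peaks off. Among the 78 Uextra peaks scoring above 150, the width CV was 16.4%, against 51.6% for the 156 arm peaks above that score and at least 42.8% in 10000 random draws of as many arm peaks. Those 156 include the 23 wide peaks of the 2L array (lowest score 167.51, widths 3404 to 5361 bp), which were not left out. Copies of a repeated sequence that share reads could give such widths, and so could short scaffolds whose ends cut the peaks off, since 2.34% of Uextra peaks exceeded 1000 bp against 36.4% on the arms. These 2 explanations cannot be told apart here, because no scaffold boundaries or sequence were used. Scaffold ends would limit the widths, but would give a narrow band only if the scaffolds were of similar length, which is not known. Reads from another organism and a biological cause were not tested.

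The lower density on X (0.84 times the other arms) stays open to 3 explanations. Without 2 Mb at the centromere side of each long arm the fold was 0.873; its upper binomial limit of 0.93, the first bound set, argued against a sparse stretch there as the whole cause, but that limit was set aside because the binomial test called X in 19.5% of simulated clustered lists with no difference. Resampled windows gave upper limits of 0.986 (100 kb, unadjusted permutation p = 0.034, against 0.0057 with all peaks) and 0.999 (500 kb, unadjusted permutation p = 0.062, against 0.023), where the 500 kb fold went from 0.849 to 0.876, so this cannot be told apart at this number of windows. Clustering of peaks makes the count look more precise than it is; with all peaks the permutation p adjusted over 6 arms was 0.017 with 100 kb windows and 0.07 with 500 kb windows, which also cannot be told apart. Fewer X copies in a population with males may also lower both scores and calls: the 90th percentile score on X was 0.799 times that of the other arms, and the density fold was 0.59 among the 25% and 0.466 among the 10% of peaks with the highest scores, but also 0.879 among peaks at or below the median score; this stays open, since no read depth was used and chromosome 4, whose copies do not differ between the sexes, had a ratio of 0.69.

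The run of 23 wide peaks on 2L was weighed in the same way. The array was taken as the longest run of wide peaks, with limits on width and step chosen after the positions had been seen. When the widths were dealt at random among the peaks of each arm, the longest run in 1000 deals was 5. Within those limits, this argues against a chance run. Tandem copies of a unit of fixed length would give equal steps, and 95.5% of the array's steps lay within 10% of their median. A comparison with other steps between wide peaks could not decide this, since there were only 5 of them. The array's own steps do show near-equal spacing. Of its 22 steps, 21 averaged 5050 ± 201 bp (SD over steps), and the longest was 13632 bp. Whether the sequence beneath the peaks is itself repeated stays open, because no sequence was used. Reads shared between near-identical copies could also even out the scores, whose CV was 8.64% against 38.8% (median) and at least 19.4% in random draws of other wide peaks; this cannot be told apart from equal binding at each copy without the reads. A biological explanation was not tested.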

How the results depend on the processing

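Windows, arm length from position 1, the list without the 2L array, and all alternatives for the scores on X and Uextra were chosen after seeing the data. No paired analysis was possible because the peak list carries no values per library or replicate, and for the same reason no replicate could be left out. The alternatives that need gene annotation or sequence of release 5 were not run. Of the 44 alternatives with a test, 36 kept both the direction and the side of the threshold, and none turned a direction. Many of those 36 were for 2L, 3L and 3R, which missed the threshold in the main test and missed it again. Merging overlapping peaks could change nothing, since none overlapped. Among peaks above the median score (3859 peaks), median width was 1189 bp and median score 58.42. Selection by score requires only the higher score, and the greater width goes with the correlation of score and width. For density, the alternative took the 3649 arm peaks above the median score of arm peaks. There, chromosome 4 had 1.07 times the density of the other arms (exact test, adjusted p = 0.63). For 3R it was 1.12 times (exact test, adjusted p = 0.0084, the only one of its alternatives to pass). Merging peaks within 1 kb gave 1.18 for chromosome 4 (exact test, adjusted p = 0.21). Permutation of 100 kb windows gave 1.39 for chromosome 4 (adjusted p = 0.18). Permutation of 500 kb windows gave 1.46 for chromosome 4 (adjusted p = 0.24), 1.17 for 2R and 0.849 for X (both adjusted p = 0.07). Over their alternatives the adjusted p ran from 0.0023 to 0.63 for chromosome 4, 0.0084 to 0.65 for 3R, 2.6e-08 to 0.07 for 2R and 8.7e-08 to 0.07 for X. With medians in place of the 90th percentile, the score ratio of X to the other arms was 0.931 (permutation test, adjusted p = 0.21). The cause was not tested. Spacing stayed below random (ratio 0.43 to 0.58). Unknown depth limits every statement about weak or missing peaks.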

Other observations

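All tests in this part were chosen after the peak list had been seen.

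TBP peaks thinned out towards the centromere on 4 of the 5 long arms. The last 1 Mb on the centromere side held 23 peaks on 2L, 32 on 2R, 8 on 3L and 11 on X, or 0.39, 0.45, 0.14 and 0.20 times the density of the middle of the same arm. On 3R the same stretch held 77 peaks, 1.23 times the middle. The opposite end of 3L was the richest, with 113 peaks in 1 Mb, 1.93 times its middle. With stretches of 2 Mb the centromere side of 2L was at 0.93 times its middle; the array of wide peaks described for 2L lies in that stretch.

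Over all arm peaks, no correlation between the scores of adjacent peaks was detected. Spearman's rho between the scores of adjacent peaks was -0.01 on the arms, inside the range of -0.04 to 0.05 from 1000 shuffles of the scores within arms. After peaks within 1 kb were merged it was 0.01. These values are averages over all arms and do not describe single regions.

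A candidate explanation for the 2L array, in which 95.5% of steps lay within 10% of the median step, is the tandem cluster of replication-dependent histone genes. In the release 6 gene table these genes are all on 2L. They number 111, with 23 copies of His1, the linker histone gene, and 24 other genes lie between the first and the last of them. The longest uninterrupted run of histone genes in that table is 5, which is also the number of histone kinds counted. Whether such runs hold 1 gene of each kind was not checked. The array also has 23 wide peaks, but that count depends on the 3000 bp minimum (29 peaks of any width lie in the span) and 1 step of 13632 bp interrupts it, so the equal counts carry little weight. Its release 5 position was not matched to any gene, so this is a hypothesis left untested here; placing the span on a release 5 annotation would test it.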
